A study of Mus musculus with 3 samples.

How the data were processed

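RNA of 3 cell fractions sorted by fluorescence from the olfactory epithelium of Tgn1-2G transgenic mouse pups of both sexes, at postnatal days 5 to 8, was hybridised to 1 array per fraction. The fractions held 1000000 strongly GFP positive cells (GFP+++), 1300000 weakly GFP positive cells (GFP+) and 6800000 GFP negative cells (GFP-). The labels give the number 32 for each fraction, read here as mice, and do not say whether the fractions came from the same mice. Total RNA was isolated with TriReagent and turned into biotin-labelled cRNA by the Affymetrix manual, per the labels' protocols.

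The deposited values are signal intensity values on a linear scale, 1 per probe set, made by the authors with MAS5, per the submitters' processing notes. The version of MAS5 and its settings are not given in the sources used here. The 2% trimmed mean of the deposited intensity values was 500.0 on each array, so each array carries 1 global scaling factor. No detection calls were used here, so a probe set without signal still has a positive value. A probe set with a value near the background therefore gives no reliable ratio, and for this reason low values were raised to a floor. MAS5 makes no correction of differences in shape between arrays, which leaves list medians of bright genes open to array effects.

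The probe names are those of the Affymetrix Mouse Genome 430 2.0 design. Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none. Of the probe sets with 1 symbol, 34741 were matched through the Entrez identifier to the RefSeq gene table of the mouse assembly GRCm38.p6. This changed 0 symbols, and no coordinates were used. The 64 control probe sets were kept out of the gene table. For each of the 18193 genes the probe set with the highest mean signal over the 3 arrays was used, and 9183 genes had 1 probe set.

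Arrays were scaled to a common 2% trimmed mean, which left the deposited values all but identical. Signals under the pooled median signal of 104 were raised to that floor, and log2 folds were taken between arrays. A gene was counted as higher or lower at a fold of 2 or more, and genes under the floor on both arrays were not counted. The floor was passed on at least 1 array by 12331 genes. Where 1 of the arrays lay under the floor, the fold is a lower bound and is written as at least that many fold.

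Each group had 1 array, so there is no spread between replicates, no test and no p-value, and every difference has no replicate check. The number of arrays limits the precision. The error of the array measurement alone was estimated from genes with several probe sets above the floor on both arrays. The pooled SD of the log2 folds of probe sets of a gene was 0.30 for GFP+++ against GFP- (4633 genes), 0.24 for GFP+ against GFP- (4979 genes) and 0.30 for GFP+++ against GFP+ (4640 genes). It holds nothing of the spread between animals, sorts or labelling reactions.

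Before the data were examined, 29 gene lists were fixed. They hold markers of immature and mature olfactory sensory neurons (OSN), of the other cell types of the mucosa and blood, and of cell processes. The cell type lists rest on general knowledge, and no gene stood in more than 1 list among those measured. A list member was measured if it passed the floor on at least 1 array. The median log2 fold of a list was placed among those of 10000 random lists of the same size, matched on mean signal in 20 bins. The resulting percentile describes these arrays and not the conditions. Members under the floor on 1 array entered the median at their bound, so that the median of a list with many such members understates its size.

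The rule for the genes named was also fixed before. In each direction of GFP+++ against GFP-, it took the 8 largest folds measured on both arrays and the 4 brightest genes whose dimmer array lay under the floor. For the other 2 comparisons it took 5 and 3. Only genes with a proper symbol were eligible, and their probe sets above the floor had to go the same way. Up to 4 of the brightest members stand as examples for a list, and Neurog1, Gap43 and Omp are always given. Other list members named below, beyond these, were chosen after their values were seen.

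The steps were tested on simulated arrays for GFP+++ against GFP-, over 18193 genes with an SD of 0.214 per array on the log2 scale. The altered genes were drawn only from those with a mean signal of at least 2 times the floor. Every probe set had the same SD, taken from probe sets above the floor on both arrays. The rates therefore do not cover error particular to dim genes. Of the genes raised 3-fold, 48 of 50 passed the 2-fold rule, as did 48 of 50 of those lowered 3-fold. Of those changed 1.5-fold, 1 of 50 raised and 2 of 50 lowered genes passed, and so did 14 of 11664 unaltered genes (0.12%). Of 100 random lists without a shift, 2 fell outside the central 95% of their random lists. The simulated error was drawn independently for each probe set, so that rate does not cover lists whose genes vary together.

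Alternatives were scaling each array by its median, quantile normalization, the values as deposited, floors at the 40th and 65th percentile of the pooled signals, and a pseudocount of 26.1 in place of a floor. Further alternatives were the median over the probe sets of a gene, the omission of probe sets that can bind several transcripts by their name (suffixes _x_at and _s_at), a fold of 3, and other rules for list members. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.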

Results

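Gene expression was measured in 3 fractions of olfactory epithelium cells that had been sorted by GFP brightness from neonatal Tgn1-2G mice. The transgene is known from other work to carry GFP under control elements of Neurog1, a proneural transcription factor of olfactory progenitors. By the submitters' account the GFP+++ fraction was enriched in immature neurons and the GFP+ fraction slightly enriched in mature ones, and the GFP- fraction held all cell types with fewer immature neurons. Each fraction was measured on 1 array, so the values below have no replicate error, and folds describe these arrays.

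The arrays differed in how many genes gave signal. The median signal was 88.2 in GFP+++, 107 in GFP+ and 118 in GFP-, and 10734, 11674 and 12031 genes lay above the floor. Across genes, Spearman's rho was 0.897 between GFP+++ and GFP-, 0.975 between GFP+ and GFP-, and 0.936 between GFP+++ and GFP+, with genes not being independent replicates. The ratio of 3' to 5' signal of the beta-actin controls, a measure of RNA integrity, was 1.46 in GFP+++, 1.31 in GFP+ and 1.43 in GFP-. For Gapdh it was 0.726, 0.717 and 0.644. The 18S ribosomal RNA controls gave 1893 in GFP+++, 4963 in GFP+ and 8310 in GFP-, so GFP- was 4.39-fold above GFP+++. The spiked bacterial and phage controls gave 976, 510 and 1182 on the same arrays.

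GFP+++ against GFP- asks what sets the fraction rich in immature neurons apart from the rest of the epithelium. Markers of immune cells, connective tissue, glands, glia, basal cells and dividing cells were far lower in GFP+++, while the medians of immature neuron markers and of cholesterol synthesis genes lay moderately above 0. Lyz1, a lysozyme gene, was 48.9-fold lower, on a probe set whose name ending marks possible binding to several transcripts. Col3a1, a fibrillar collagen, was 35.2-fold lower. Gap43, the growth cone protein of immature OSN, was 1.76-fold higher, with signals of 11233 in GFP+++, 6006 in GFP+ and 6395 in GFP-. Omp, the marker of mature OSN, was 1.54-fold lower (5041 in GFP+++ against 7748 in GFP-).

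In all, 235 genes were at least 2-fold higher in GFP+++ than in GFP- and 1522 were at least 2-fold lower, of 12235 genes compared. Of the lower genes, 620 lay under the floor in GFP+++. Where a gene had a second probe set above the floor on either array, it went the same way for 69 of 74 higher and 572 of 585 lower genes. If that probe set lay under the floor on the other array, its direction was fixed by passing the floor. The split depended on the scaling: with each array scaled by its median it was 1129 higher against 1045 lower, and the lower share of the calls went from 86.6% to 48.1%. The median log2 fold of all genes then lay at 0.41, and each gene above the floor on both arrays moved by 0.42. List medians below are as measured with the trimmed-mean scaling. Where a list's direction turned with the median scaling, its distance from the median of all genes is given under both. That scaling also moved how many genes of a list passed 2-fold. At least 2-fold higher were then 10 cholesterol synthesis, 6 immature OSN, 6 axon guidance, 5 cilium assembly, 4 synaptic vesicle and 4 OSN transcription factor genes, and at least 2-fold lower 14 cell cycle, 6 immediate early and 6 sustentacular genes. The other list counts of this comparison differed by fewer than 3 from those below.

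**Figure D1:**
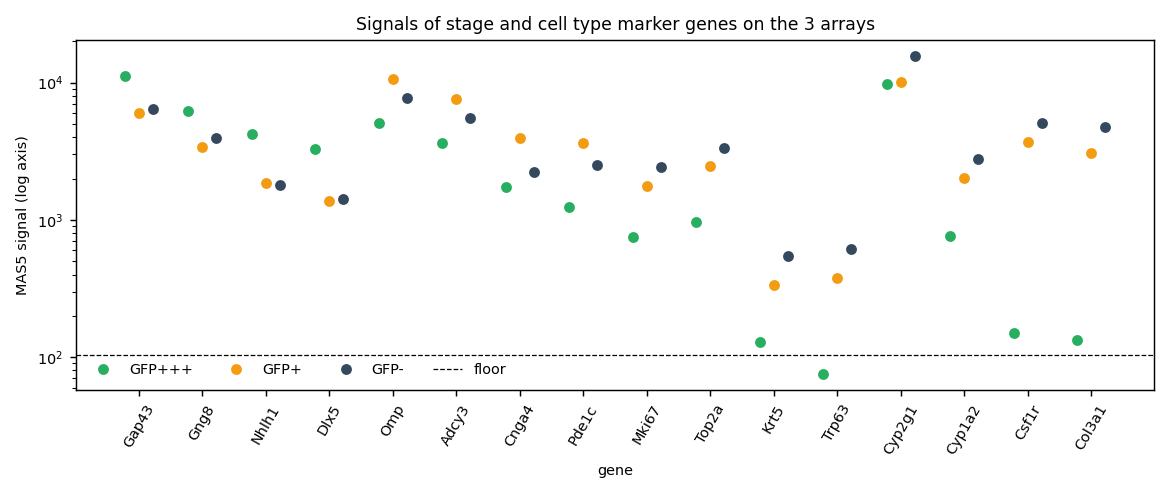
MAS5 signal on a log axis of 16 marker genes on the 3 arrays, 1 point per array, with the floor as a dashed line. Gap43 lies highest in GFP+++ (11233) and Omp highest in GFP+ (10615), while Csf1r and Col3a1 are near the floor in GFP+++ alone (151 and 134).

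Of the 16 measured immature OSN genes, 14 lay above 0, with a median log2 fold of 0.36 (percentile 99.9), but Crmp1 alone was at least 2-fold higher (log2 1.07), against 6 genes with median scaling and 0 with quantile normalization, and only Chl1 at least 2-fold lower (at least 2.79-fold). Of the 4 brightest members, the microtubule and cytoskeleton regulators Stmn1 (log2 -0.06), Stmn2 (0.24) and Dpysl3 (0.14) differed little, while Gap43 was at 0.81. The OSN transcription factors had a median of 0.27 over 13 genes (percentile 97.1), with Dlx5 at 1.21, Lhx2 at 0.27, Ebf2 at 0.05, Ebf3 at 0.17 and Atf5 at -0.01. Among 12 neurogenic transcription factors the median was -0.09, which turned to 0.32 with median scaling and 0.01 with quantile normalization, but relative to all genes was -0.10 with the trimmed, -0.09 with the median and -0.04 with the quantile scaling. Nhlh1, a factor of newly formed neurons, was 2.35-fold higher, and Eya2 was lower at a log2 fold of -2.08. Neurog1 itself, whose control elements the transgene is known to use, had a log2 fold of 0.31 (1492 in GFP+++ against 1202 in GFP-).

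Of 18 mature OSN genes, 0 were at least 2-fold higher and 2 at least 2-fold lower, Pde1c (log2 -1.02) and Ncam2 (-2.40). Their median was -0.40 (percentile 0). With median scaling it was 0.01, while relative to all genes it was -0.41 and -0.40 under the trimmed and median scalings. S100a5, a calcium binding protein of mature OSN, was at -0.75, Gnb1 at -0.08, Stoml3 at -0.46 and Gng13 at -0.08. Cilium assembly genes had a median of 0.24 over 33 genes (percentile 94.8), with Ift43 at 0.63, and synaptic vesicle genes 0.23 over 21 (percentile 92.2), with Stx1a at 0.83. In both lists 0 genes passed 2-fold, against 5 and 4 with median scaling.

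Axon guidance and adhesion genes parted: of 39, 2 were at least 2-fold higher and 5 at least 2-fold lower, with a median of 0.07 (percentile 76.8). Cntn2, an axonal adhesion molecule, was 4.60-fold higher and Dcc, a netrin receptor, 3.23-fold higher. The lower ones were Nrp2 (log2 -1.33), Epha5 (-1.49), Slit2 (-1.48), Plxna2 (at least 2.63-fold lower) and Sema3c (at least 2.53-fold lower). Of the brightest members, Ncam1 (0.17), Cntn4 (0.03) and Plxnb2 (0.28) lay near 0, and Pcdh8 was at -0.44.

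All 26 cell cycle genes were lower in GFP+++, 20 of them at least 2-fold, with a median log2 fold of -1.48 (percentile 0). Mki67, the common proliferation marker, was 3.25-fold lower and Top2a, the topoisomerase of replicating cells, 3.47-fold lower, while the bright members Pcna (-0.98) and Mcm7 (-0.45) stayed within 2-fold. Horizontal basal cell genes, of the resting stem cell layer, had a median of -1.49 over 12 genes (percentile 0), 8 of them at least 2-fold lower and 9 of them bounds. Krt5 was 4.23-fold lower, and Trp63, the basal cell regulator, at least 5.85-fold lower. Chromatin regulators had a median of -0.15 over 26 genes (percentile 0.19), which turned to 0.27 with median scaling but stayed at -0.15 relative to all genes. Of these, 3 were at least 2-fold lower: Uhrf1 (-2.08), Cbx5 (-1.45) and Dnmt3b (-1.26). Hmgn1, Hdac2, Rcor1 and Smarca4 lay at -0.13, 0.24, 0.57 and 0.44. Histone genes had a median of 0.06 over 10 (percentile 73.6), with H2bc21 at 0.06 and H2ac19 at 0.49.

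The supporting and gland cells were lower to different degrees. Sustentacular genes had a median of -1.33 over 16 genes, 11 of them at least 2-fold lower. The brightest by mean signal lay within 2-fold, Sult1c1 at -0.20, Cbr2 at -0.67, Cyp2g1 at -0.67 and Sec14l3 at -0.81, while Cyp2f2 (-1.69) and Epas1 (-1.32), also above a signal of 10000 in GFP-, did not. All 12 Bowman gland and secretory genes were at least 2-fold lower (median -3.25, with 5 bounds), among them Bpifa1 (-2.07), Lcn11 (-3.50), Ltf (-3.29) and Aqp3 (-1.43). Of 8 microvillar cell genes 6 were at least 2-fold lower (median -1.55, with 3 bounds), such as Ascl3 (-2.71) and Coch (-1.22). Respiratory ciliated cell genes had a median of -0.32 over 11 (percentile 17.0), which turned to 0.09 with median scaling but was -0.33 and -0.32 relative to all genes, with Mlf1 at 0.31 and Rsph1 at 0.03.

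Of the cells of the lamina propria and blood, 20 of 21 immune genes were at least 2-fold lower, 14 of them bounds, so the median corresponds to at least 11.3-fold. Csf1r, the macrophage growth factor receptor, was 33.5-fold lower, and the neutrophil genes S100a8 and S100a9 were 30.2-fold and at least 34.7-fold lower. Fibroblast and matrix genes were at least 2-fold lower for 14 of 15 members, with a median log2 fold of -3.61. Among them Sparc was 30.1-fold, Col1a2 16.9-fold and Dcn 9.38-fold lower. Ensheathing glia and Schwann cell genes had a median of -1.79 over 13, with 9 at least 2-fold lower and 8 bounds, so the median corresponds to at least 3.46-fold. Fabp7 (-2.14) and Apod (-3.36) were among the lower ones, and Mbp was higher at 0.82. Endothelial and pericyte genes had a median of -0.63 over 11 (percentile 5.71, with 6 bounds), with 4 at least 2-fold lower, such as Rgs5 (-2.00). Of 6 erythroid genes 3 were at least 2-fold lower (median -0.76, percentile 3.13): Fech (625 against 1252), Alas2 (at least 6.18-fold) and Slc4a1 (at least 3.67-fold). Percentiles not given in this paragraph and the one before it were at most 0.02.

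**Figure D2:**
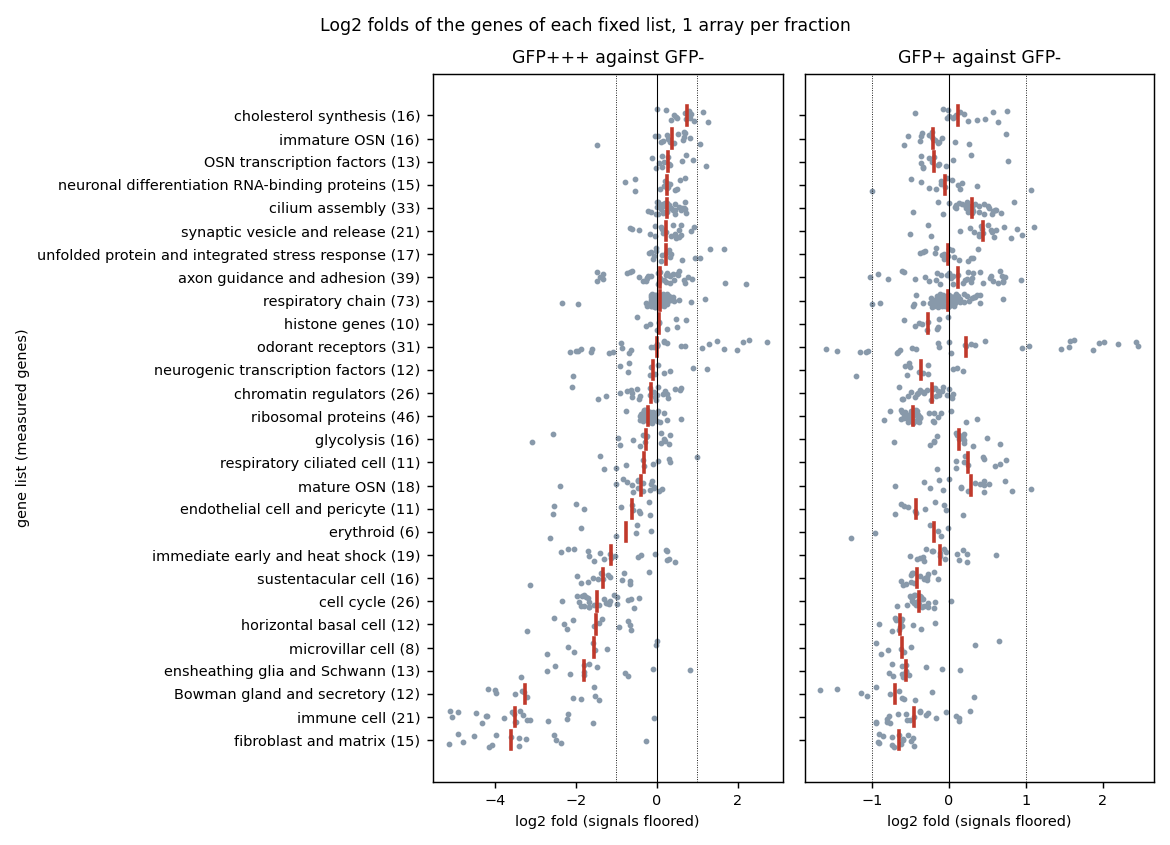
Log2 folds on floored signals of GFP+++ against GFP- (left) and GFP+ against GFP- (right), 1 grey point per measured gene of each list, red bars at the list medians and dotted lines at a fold of 2. Fibroblast and immune genes lie lowest on the left (medians -3.61 and -3.50) and cholesterol synthesis genes highest (0.75), while odorant receptors spread to both sides.

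Among the processes, all 16 cholesterol synthesis genes lay above 0, with a median log2 fold of 0.75 (percentile 100). Cyp51 (1.26) and Mvk (1.15) passed 2-fold, and Hmgcs1, Fdft1, Fdps and Sqle were at 0.49, 0.71, 0.81 and 0.23, and with median scaling 10 genes passed. Of 17 genes of the unfolded protein and integrated stress response, 3 were at least 2-fold higher: Trib3 (1.30), Chac1 (1.06) and Sesn2 (at least 3.18-fold). The other 14 stayed within 2-fold, among them Ddit3 (0.93), Atf4 (0.63), Ddit4 (0.33) and Asns (0.11). The chaperone Hspa5 (-0.20), Xbp1 (-0.02), Calr (-0.10) and Dnajb9 (-0.06) lay near 0, and the list median was 0.22 (percentile 93.7). Immediate early and heat shock genes had a median of -1.13 over 19 (percentile 0), with 11 at least 2-fold lower. Fos (-1.13), Egr1 (-1.30) and Nr4a1 (-2.20) were among these, whereas Jun (0.25), Jund (0.22) and Dusp1 (0.29) were not.

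Glycolysis genes had a median of -0.28 over 16 (percentile 0.15), which turned to 0.14 with median scaling but stayed at -0.28 relative to all genes. Of these, 2 passed 2-fold, Hk2 (-3.09) and the glucose transporter Slc2a3 (at least 5.94-fold lower), and the bright members Ldhb (0.21), Pkm (0.32), Tpi1 (0.10) and Aldoa (-0.42) did not. Ribosomal protein genes had a median of -0.21 over 46 (percentile 0), which turned to 0.20 with median scaling but was -0.22 and -0.21 relative to all genes, and 0 passed 2-fold, Rpl38 being at -0.12 and Rps29 at -0.11. Respiratory chain genes had a median of 0.07 over 73 (percentile 72.8), with Ndufb4 (1.18) higher and Cox8b (-2.35) and Cox6b2 (-1.94) lower. RNA-binding proteins of neuronal differentiation had a median of 0.25 over 15 (percentile 93.2), with Elavl3 at 0.27 and Msi1 at 0.22.

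By the rule for named genes, which leaves out genes whose probe sets go opposite ways, the largest folds of GFP+++ over GFP- measured on both arrays were those of the odorant receptor Olfr73 (6.55-fold), Lysmd4 (5.31-fold), Bfsp2 (4.98-fold), Cntn2, Olfr749 (4.37-fold), Pwwp3b (4.17-fold), Mthfs (4.14-fold) and Olfr154 (3.96-fold). With GFP- under the floor, Olfr976 was at least 4.85-fold, the embryonic globin Hbb-y at least 3.71-fold, Sesn2 at least 3.18-fold and Kcnip2 at least 3.13-fold higher. Besides Lyz1, Col3a1, Csf1r, S100a8 and Sparc, the lowest measured genes by that rule were Col5a2 (27.7-fold), Bpifb3 (26.3-fold) and Lum (23.0-fold). The secreted protein gene Bpifb9b was at least 121-fold, Srgn at least 27.1-fold and Mgp at least 24.2-fold lower. Under the 65th percentile floor 7 of these 12 higher genes lay under 2-fold: Cntn2 (0.92), Olfr976 (0.88), Olfr154 (0.87), Mthfs (0.71), Hbb-y (0.49), Sesn2 (0.27) and Kcnip2 (0.24). With the median over probe sets Cntn2 and Kcnip2 did, at 0.46 and 0.00. Lyz1, S100a8 and Hbb-y had no value without probe sets of the suffixes _x_at and _s_at, so cross-binding was not checked for them.

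Odorant receptors, of which a mature neuron uses 1, parted most. Of 31 measured receptors 8 were at least 2-fold higher and 8 at least 2-fold lower in GFP+++ than in GFP-, with 17 bounds. The median log2 fold of 0.00 was set by 4 receptors under the floor on both arrays, and without these it was -0.07. Higher ones included Olfr672 (1.28) and Olfr78 (1.49), and Olfr870 was at 0.16. Lower ones included Olfr140 (at least 4.40-fold) and Olfr1508 (at least 4.01-fold). Of the 32 vomeronasal and trace amine receptor genes on the array only Vmn2r29 passed the floor, in GFP+ alone (125).

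**Figure D3:**
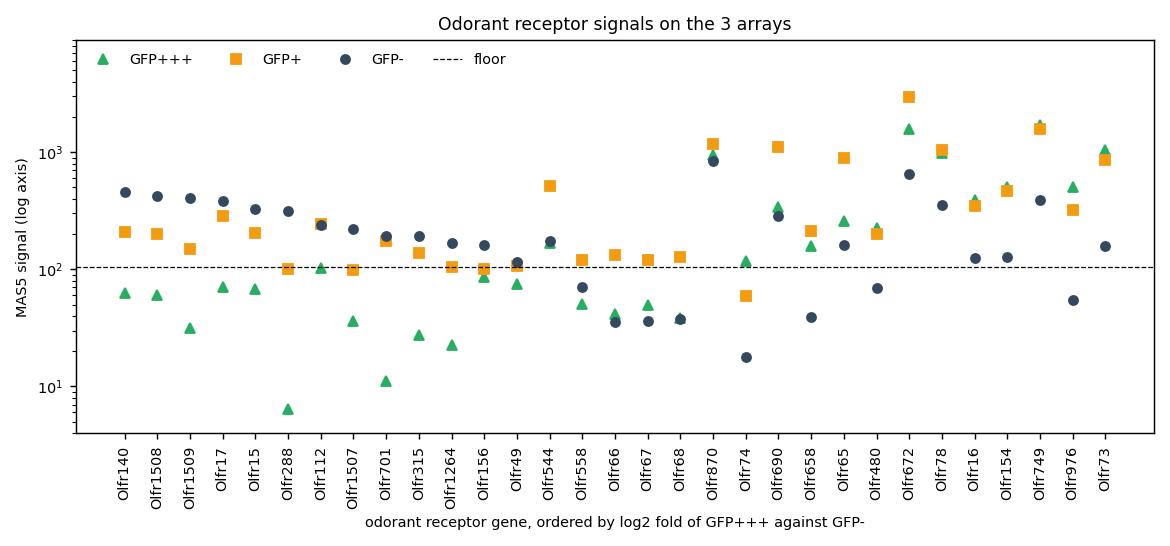
MAS5 signal on a log axis of the 31 measured odorant receptor genes on the 3 arrays, 1 point per array, ordered by the log2 fold of GFP+++ against GFP-, with the floor as a dashed line. Receptors at the right, such as Olfr73, lie higher in both GFP positive fractions (1040.0 and 861) than in GFP- (159), and those at the left lie lower.

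GFP+ against GFP- asks what the weakly fluorescent cells held beyond the unlabelled ones. The arrays were alike in most genes, but the medians of mature neuron, synaptic and cilium genes lay above 0 and those of glands, immune, connective tissue and basal cells below 0, by less than in GFP+++. Of these neuronal lists 1 of 18 mature neuron, 1 of 21 synaptic and 0 of 33 cilium genes passed 2-fold, and with median scaling 3 synaptic genes did. Omp had a log2 fold of 0.45 (10615 against 7748), Gap43 -0.09, which turned to 0.05 with median scaling and with quantile normalization, and Neurog1 0.18. In this comparison 74 genes were at least 2-fold higher and 98 at least 2-fold lower, of 12196. With median scaling the split was 131 against 46 and the median of all genes 0.12, and the lower share went from 57.0% to 26.0%. A second probe set went the same way for 19 of 19 higher and 27 of 29 lower genes.

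Mature OSN genes had a median log2 fold of 0.29 (percentile 100), with 12 of 18 above 0. Faim2 (1.07) was the member past 2-fold. The brightest members, S100a5 (-0.33), Gnb1 (-0.25), Stoml3 (-0.13) and Gng13 (0.16), stayed within 2-fold. Synaptic vesicle genes had a median of 0.45 (percentile 100), with Syngr3 (1.11) past 2-fold, Snap25 at 0.32 and Syt1 at 0.41. Cilium assembly genes had a median of 0.30 (percentile 99.99), respiratory ciliated cell genes 0.25 (percentile 98.4) and axon guidance genes 0.12 (percentile 99.1). Immature OSN genes had a median of -0.21 (percentile 4.15), neurogenic transcription factors -0.36 (percentile 0) and OSN transcription factors -0.19 (percentile 7.88).

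Of the non-neuronal lists, Bowman gland genes had the lowest median (-0.71, with 4 of 12 at least 2-fold lower), followed by fibroblast (-0.65), horizontal basal (-0.63), microvillar (-0.61), glia (-0.56), immune (-0.45), sustentacular and endothelial (both -0.42) and cell cycle genes (-0.39). In 8 of these 9 lists no gene passed 2-fold. Erythroid genes were at -0.20. Ribosomal protein genes had a median of -0.47 (percentile 0), histone genes -0.28 and chromatin regulators -0.22. Cholesterol synthesis was at 0.12 (percentile 88.4) and glycolysis at 0.13 (percentile 95.2). Medians near 0 whose direction turned with a scaling were those of the stress response (-0.01), the respiratory chain (-0.01), immediate early genes (-0.11) and RNA-binding proteins (-0.05). Relative to all genes these were -0.0092, -0.0026, -0.10 and -0.04 with the trimmed and -0.05, 0.012, -0.09 and -0.03 with the median scaling.

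Odorant receptors parted in GFP+ against GFP- too. Of 31, 11 were at least 2-fold higher and 5 at least 2-fold lower, with a median of 0.22 (percentile 100). The counts were 11 and 3 of 30 with median scaling, and 10 and 4 of 30 with quantile normalization. By the rule for named genes, the largest folds were those of Tafa4 (5.97-fold), Olfr65 (5.52-fold), Olfr73 (5.42-fold), Olfr672 (4.58-fold) and Olfr749 (4.04-fold). Olfr976 was at least 3.09-fold, Ppp1r32 at least 2.65-fold and Ammecr1 at least 2.30-fold higher. The lowest by the same rule were the secreted proteins Bpifb5 (8.21-fold) and Bpifb9b (3.61-fold), the odorant binding proteins Obp1a (3.18-fold) and Obp2a (2.73-fold), and Olfr1509 (2.74-fold). Ttr was at least 5.45-fold, Clec2d at least 3.15-fold and Olfr288 at least 3.03-fold lower. Under the 65th percentile floor Olfr976, Ppp1r32, Olfr1509, Clec2d and Olfr288 lay under 2-fold and Ammecr1 lay under the floor, and with the median over probe sets Ammecr1 was at 0.60.

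GFP+++ against GFP+ compares the fraction rich in immature neurons with the one slightly enriched in mature ones. The median of immature neuron genes lay above 0 and that of mature ones below 0, as did the median of every list of non-neuronal cells. Gap43 had a log2 fold of 0.90, Omp -1.07 and Neurog1 0.13, for which the median over probe sets gave -0.02. Here 117 genes were at least 2-fold higher and 1109 at least 2-fold lower, of 11881 (90.5% lower). Median scaling gave 416 against 767 (64.8% lower), with the median of all genes at 0.23. A second probe set went the same way for 37 of 39 higher and 418 of 428 lower genes.

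Immature OSN genes had a median of 0.51 (percentile 100), with 14 of 16 above 0 and Tubb2b (1.05) past 2-fold. OSN transcription factors were at 0.43 (percentile 99.9), with Dlx5 at 1.25, and neurogenic transcription factors at 0.26 (percentile 94.9), with Nhlh1 at 1.18. Mature OSN genes had a median of -0.65 (percentile 0), with 1 of 18 above 0 and 6 at least 2-fold lower: Pde1c (-1.55), Ncam2 (-1.70), Slc24a4 (-1.20), Cnga4 (-1.18), Omp and Adcy3 (-1.05). Synaptic vesicle genes were at -0.29 (percentile 0.74). Cholesterol synthesis genes were at 0.51 (percentile 100), with Mvd (1.14) past 2-fold, and histone genes at 0.36 (percentile 99.1).

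Cell cycle genes had a median of -1.09 with 14 of 26 at least 2-fold lower, immediate early genes -0.88 with 9 of 19, and sustentacular genes -0.94 with 7 of 16. The medians of immune (at least 8.05-fold), fibroblast (-2.95), Bowman gland (-2.51), glia (at least 2.36-fold), horizontal basal (-1.10), respiratory ciliated (-0.92), microvillar (-0.69), erythroid (-0.58) and endothelial genes (-0.55) were all lower in GFP+++. Glycolysis genes were at -0.40, ribosomal protein genes at 0.25, stress response genes at 0.26 and RNA-binding proteins at 0.29. Odorant receptors were at -0.29 (percentile 1.39), with 0 at least 2-fold higher and 5 at least 2-fold lower. Axon guidance (-0.11), chromatin (0.05), cilium assembly (-0.03) and respiratory chain genes (0.08) had medians whose direction turned with a scaling. Of these, axon guidance and cilium assembly genes turned with median scaling, and relative to all genes were -0.11 and -0.03 with the trimmed and -0.13 and 0.012 with that scaling. With median scaling 6 immature OSN genes were at least 2-fold higher, and 9 cell cycle, 4 sustentacular, 2 mature OSN and 2 respiratory ciliated genes at least 2-fold lower.

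By the rule for named genes, the largest measured folds of GFP+++ over GFP+ were those of Cntn2 (4.43-fold), Bfsp2 (4.32-fold), Pwwp3b (3.07-fold), Rimklb (2.98-fold) and Cnpy1 (2.97-fold). Npr3 was at least 3.40-fold, Sncaip at least 2.61-fold and A4galt at least 2.12-fold higher. Under the 65th percentile floor Cntn2 and Npr3 lay under 2-fold and Sncaip and A4galt under the floor, and with the median over probe sets Cntn2, Rimklb, Npr3 and Sncaip lay under 2-fold. With the pseudocount A4galt did, at 0.94. Lyz1 (41.9-fold), S100a8 (29.4-fold), Csf1r (24.5-fold), Col3a1 (22.9-fold) and the protease gene Ctss (19.9-fold) were lowest, Lyz1 and S100a8 again with no value without the suffixed probe sets. S100a9 was at least 41.98-fold, Bpifb9b at least 33.4-fold and Srgn at least 25.2-fold lower.

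Across the 3 fractions, 71 genes were at least 2-fold higher in GFP+++ than in both others, 31 in GFP+ and 92 in GFP-. Another 934 genes were at least 2-fold lower in GFP+++ than in both others. Of the 1522 genes lower in GFP+++ than in GFP-, 1405 had a GFP+ signal between the other two, with all signals raised to the floor.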

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

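Tests chosen only after the result was seen were those of the brightest genes, of the sustentacular spread and the spiked controls, and of the receptor classes and the receptor spread. Those of ribosomal genes after quantile normalization, Nqo1 and the probe set suffixes were set before their values were seen. Signals outside the gene table drew attention on all arrays. Of 9160 probe sets with no gene name here, 2488 lay above the floor in GFP+++ or GFP-. Of these 2488, 109 were at least 2-fold higher in GFP+++ than in GFP- and 142 at least 2-fold lower. In the gene table these counts were 235 and 1522 of 12235 genes. In GFP+ against GFP-, 11 were higher and 25 lower of 2367 above the floor, beside 74 and 98 of 12196 genes. The spiked bacterial and phage controls, added in equal amount by the usual protocol, were 1.91-fold higher in GFP+++ than in GFP+.

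Odorant receptors lay in opposite directions, 11 at least 2-fold higher and 5 at least 2-fold lower in GFP+ than in GFP-. A different share of mature neurons alone would move them one way, which these opposite folds argue against, with an SD of 1.22 against 0.24 between probe sets of a gene. That 0.24 rests on probe sets above the floor on both arrays, whereas 10 of the 31 receptors were bounds, so error at dim signals was not measured. Of the 20 receptors above the floor on both arrays, 9 were at least 2-fold higher and 3 at least 2-fold lower. Cross-binding probe sets stay open, since 0 of the 16 receptors past 2-fold in GFP+++ had a name ending that marks it and its omission left 8 in each direction. A hypothesis is that the GFP positive neurons came mostly from the dorsal zone of the epithelium: the dorsal gene Nqo1 had a log2 fold of 1.45 in GFP+++ against GFP-, on 1 probe set. The median of 10 class I receptors, which are used dorsally, lay 1.73 above that of 19 class II receptors in GFP+ against GFP-. In GFP+++ against GFP- it lay 1.51 above, over the 6 and 19 receptors above the floor on either array. There, though, 5 class II receptors were at least 2-fold higher, and class II lay higher among the few above the floor on both arrays. The zone of each class II receptor was not assessed, so the higher ones cannot be read for or against the dorsal zone. Zone and cross-binding both stay possible.

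Sustentacular genes were unevenly lower in GFP+++, from -0.20 for Sult1c1 to -3.13 for Aldh1a7. Carry-over would give 1 common fold only for genes used in these cells alone. The SD over the 16 genes was 0.67, against 0.30 between probe sets of a gene. Without Sox2, Hes1, Krt8, Krt18 and Epas1, which other cells are known to use, the SD over 11 genes was 0.80. That spread argues against carry-over alone only if these 11 genes are used in sustentacular cells alone, which was not tested. Uneven folds were not particular to this list: fibroblast genes ran from -0.27 for Col6a1 to -5.14 for Col3a1. The 6 genes with a signal of 10000 or more in GFP- had a median of -0.74 and the 10 dimmer ones -1.41, which goes with a flattening of bright signals. Flattening alone on the GFP- array is argued against by the spiked controls. Their bright probe sets kept 0.853 of the log2 difference of the dim ones between GFP+ and GFP-. Between GFP+++ and GFP- the controls differed too little to test it (-0.27 dim, -0.36 bright), and the also bright Bpifa1, Col1a2 and Rgs5 were lower by log2 folds of -2.00 to -4.08. Use of bright sustentacular genes in neurons, or carry-over together with another process, remains possible and was not tested.

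Ribosomal protein genes were lower in GFP+ than in GFP-, with a median of -0.47. Whether a response of the GFP+ array that depends on brightness may account for part of it stays open. The brightest 10% of genes outside the lists had a median of -0.074, short of the limit set for such a response. The 2 dimmest of 10 brightness groups were lower still, both at -0.18. These dim groups cannot decide it, since a gene above the floor in GFP- alone could only be lower. More genes passed the floor in GFP- (12031) than in GFP+ (11674). Quantile normalization brought the ribosomal median to -0.12, near the limit set for such a response but not within it. An array effect and a difference between the cells cannot be told apart here, because each fraction had 1 array.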

How the results depend on the processing

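All alternatives below were set before the data were examined. No paired analysis was possible because each fraction had 1 array and no test, and no array could be left out. Of 171 values of the main counts and list medians under the alternatives, 119 kept their direction and stayed within 1.5 times or within their spread, 18 medians moved further, 23 counts were smaller, 10 were larger and 1 median reversed. Of 1262 values of other lists and named genes, 990 stayed, 264 moved and 8 reversed. A value counts as reversed where its sign turned and it had lain at least 1 SD from 0, of random list medians for a list or between probe sets for a gene. Another 11 medians and 3 values of genes nearer 0 also turned sign, among them the neurogenic transcription factors of GFP+++ against GFP-. The values as deposited, the pseudocount and the other rules for list members moved none of the main results past these limits, and leaving out genes of several lists removed no gene. Signal over background limits the dim genes: a higher floor or fold leaves fewer by construction, and for the other settings the cause was not tested beyond the shift of all genes.

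With the floor at the 40th percentile, 165 genes were lower in GFP+ than in GFP-, and 151 and 48 were highest in GFP- and GFP+. At the 65th percentile, the higher and lower counts were 152 and 746 for GFP+++ against GFP-, 40 and 38 for GFP+ against GFP-, and 71 and 526 for GFP+++ against GFP+. Then 43, 17 and 35 genes were highest in GFP+++, GFP+ and GFP-, and the respiratory ciliated median of GFP+++ against GFP- turned to 0.011. At a fold of 3 the counts in the same order were 24 and 747, 11 and 10, and 7 and 409, with 5, 3 and 9 highest.

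With the median over probe sets, 76 genes were higher and 712 lower in GFP+++ than in GFP+, and 64 lower in GFP+ than in GFP-. The immature OSN median was then 0.46 in GFP+++ against GFP- and 0.62 against GFP+, and the mature OSN median -0.31 and -0.75. Without probe sets of the suffixes _x_at and _s_at the immature OSN median of GFP+++ against GFP- was 0.51, and Lyz1, S100a8 and Hbb-y had no value.

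Median scaling, which moved each gene above the floor on both arrays by 0.42 in GFP+++ against GFP-, 0.28 in GFP+++ against GFP+ and 0.14 in GFP+ against GFP-, gave 1129 genes higher in GFP+++ than in GFP-, 416 higher in GFP+++ than in GFP+, 131 higher and 46 lower in GFP+ than in GFP-, and 338 and 43 highest in GFP+++ and GFP-. The immature OSN medians were 0.78 for GFP+++ against GFP-, 0.78 for GFP+++ against GFP+ and -0.071 for GFP+ against GFP-. The mature OSN medians were 0.012, a reversal, -0.37 and 0.43 in that order, yet relative to all genes the first was -0.41 before and -0.40 after. The sustentacular medians were -0.92, -0.67 and -0.28. By the same shift the medians of chromatin regulators (0.27), glycolysis (0.14), respiratory ciliated (0.093) and ribosomal protein genes (0.20) reversed in GFP+++ against GFP-, while relative to all genes they were -0.15, -0.28, -0.32 and -0.21. Axon guidance genes reversed to 0.10 in GFP+++ against GFP+, and immediate early genes to 0.029 in GFP+ against GFP-.

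With quantile normalization, 367 genes were higher in GFP+++ than in GFP-, 179 higher than in GFP+, and 130 highest in GFP+++. The immature OSN median was 0.29 for GFP+++ against GFP+ and -0.12 for GFP+ against GFP-, the mature one -0.90 and 0.46, and the sustentacular one -0.25 for GFP+ against GFP-. The respiratory chain median of GFP+++ against GFP+ reversed to -0.10.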

Other observations

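The test of Nqo1 was set before its value was seen, and the genes below were chosen after their values were seen. In GFP+++, beside the genes of the rule, the genes at least 2-fold over both other fractions included Sox13 (990.5 against 383 in GFP+ and 382 in GFP-), a transcription factor, and Dlx6os1 (1050.0 against 407 and 403), the antisense transcript at the Dlx5 and Dlx6 locus. In GFP+ they included the glutamate transporter Slc1a2 (1242 against 263 in GFP+++ and 412 in GFP-), Tox2 (639 against 245 and 208), Bmp6 (879 against 264 and 397) and the interferon-induced gene Ifit1 (1102 against 252 and 463). The receptors Olfr65, Olfr690 and Olfr544 were also highest in GFP+, with signals of 884, 1109 and 516. In GFP-, Gfra2, a neurturin receptor, had a signal of 463 against 30.1 in GFP+++ and 170.5 in GFP+, and the tachykinin gene Tac4 had 848 against 59.3 and 339.

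The globin genes Hbb-y and Hba-a2 had different orders of signal. Hbb-y, the embryonic beta globin, had 388 in GFP+++, 150 in GFP+ and 16.7 in GFP-, Hba-a2 had 581, 428 and 837, and Alas2, the erythroid enzyme of heme synthesis, 49.7, 267 and 645. The probe set of Hbb-y has a name ending that marks possible binding to several transcripts.

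The zone hypothesis was followed in other genes known to mark dorsal or ventral neurons. Nqo1 had signals of 8351 in GFP+++, 8432 in GFP+ and 3054 in GFP-, a log2 fold of 1.45 of GFP+++ against GFP-. The dorsal gene Sema3f was at 0.92 on its brightest probe set, whose name ending marks possible binding to several transcripts. Its other probe sets were at 0.33 and 0.28. In GFP+ against GFP- its probe sets were at 0.55, -0.19 and 0.30 in the same order. In GFP+++ against GFP-, dorsal Robo2 was at least 1.40-fold higher but near the floor (146 in GFP+++). Ncam2 and Nrp2, which are known to be used ventrally, were lower at -2.40 and -1.33. The values of Robo2, Ncam2 and Nrp2 had been seen before this hypothesis was written, and Nrp2 and Ncam2 are also used in other cells or stages, so they may not speak for zone alone. The class I receptors had a median of 1.30 over 10 in GFP+ against GFP-, and the 19 class II receptors one of -0.43, with 7 above 0 and 4 at least 2-fold higher. Of the 10, Olfr558, Olfr66, Olfr67 and Olfr68 passed the floor in GFP+ alone, which fixed their sign. Over receptors above the floor on both arrays, a choice made after the values were seen, the medians were 1.96 over 5 and -0.43 over 13. In GFP+++ against GFP- those 4 were under the floor on both arrays. Of the other 6 class I receptors 5 lay above 0, with a median of 0.64 and 2 at least 2-fold higher, and the class II median was -0.87, with 5 at least 2-fold higher and 8 at least 2-fold lower. Over receptors above the floor on both of these arrays the order was the opposite, 0.70 over 5 of class I and 2.06 over 4 of class II, but that choice leaves out receptors that were under the floor in GFP+++.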
